A study of Mus musculus with 8 samples.

How the data were processed

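Total RNA was measured on Illumina BeadChip expression arrays from E14 mouse embryonic stem cells, a line derived from the inner cell mass of the early embryo that is kept undifferentiated with leukaemia inhibitory factor (LIF). Per the labels' protocols, cells grew in medium with 15% serum and 1500 U/ml LIF, were transfected with a short hairpin RNA (shRNA) and were selected with puromycin for 3 days before TRIzol extraction. The control hairpin targets GFP, and 3 different hairpins target Dnmt3l, the catalytically inactive partner of the DNA methyltransferases Dnmt3a and Dnmt3b. Groups came from the labels: shGFP, shDnmt3L1, shDnmt3L2 and shDnmt3L3, with 2 arrays each and 8 in all. The labels call the arrays of a group duplicates and do not say whether they came from separate cultures, so the p-values measure only the spread between these duplicates, which may be technical. The hairpin sequences and the chip that held each array are not given in the sources used here, so no chip effect could be tested.

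The authors' deposited non-normalized table gives 1 intensity per probe and array, the Cy3 signal averaged over beads on a linear scale without background subtraction. GenomeStudio 2011.1 is named for it in the submitters' processing notes. Per the file headers, the deposited p-value column beside each intensity is unnamed, and its values moved in steps that correspond to 936 negative controls. This column was read as the detection p-value of the intensity to its left, from its position and because it follows that intensity monotonically. A separate table holds the authors' deposited processed intensity of the same arrays. On every array its values ran from -15.4 to 25910 with a median between 6.23 and 6.24, and its rank correlation with the non-normalized signal was 1. Those values are linear, background-subtracted and set to 1 common distribution, and the steps that made them are not given in the sources used here, beyond the software name. They were used as an alternative only.

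From the non-normalized intensities, background correction and quantile normalization were done with neqc in limma 3.58.1 (R 4.3.3), which estimates the background from the detection p-values and adds an offset of 16 before log2. Because of this correction and offset, log2 differences of dim genes depend on the setting more than those of bright genes. Of 45281 probes, 34885 were paired with 1 gene by the platform annotation, 18 with several genes and 10378 were not listed there. No gene was named from those other probes. Symbols of 34807 probes were updated or kept through the gene ID with the RefSeq gene table of the mouse assembly GRCm38.p6, used for names and chromosome assignment only. Probes with a detection p under 0.05 on at least 2 arrays were kept (20754, of which 17301 had 1 gene), and each gene was represented by its probe with the highest mean, which left 10930 genes. In the comparison of the 3 hairpins with shGFP, a gene's used probe and another detected probe were both called in 1946 cases, and 140 had opposite signs. Where the used probe was called, another detected probe had the same sign in 81.9% of cases.

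All 8 arrays entered 1 limma model (lmFit, eBayes) with 4 group means, which share an estimate of the spread with 4 residual and 4.64 prior degrees of freedom. The contrasts were the mean of the 3 hairpin groups minus shGFP, each hairpin group minus shGFP, each hairpin group minus the mean of the other 3 groups, and an F test of equal means among the 3 hairpin groups. All tests were two-sided. P-values were adjusted by Benjamini-Hochberg over the genes of a contrast, and a gene was called at an adjusted p under 0.05. A gene not detected on any array of a group has only a bound there. It is given as "at least N-fold": the bright group's mean against, per array, the higher of the lowest normalized log2 value among detected probes and the dim probe's own value.

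The following 25 gene lists were tested with limma's camera at its preset correlation of 0.01, with adjustment over the lists: DNA methylation machinery, pluripotency, primed epiblast, Rhox cluster, primordial germ cell, methylation-silenced germline genes, imprinted genes, Polycomb components, bivalent homeobox genes, primitive and definitive endoderm, mesoderm, neuroectoderm, trophectoderm, fibroblast and feeder cell, two-cell-like, interferon response, p53 targets, unfolded protein and integrated stress response, ERK pathway targets, LIF STAT3 targets, Wnt targets, cell cycle, glycolysis, cytosolic ribosomal proteins and housekeeping. Camera compares a list with all other genes measured. Where it estimates the correlation instead, it also uses the 4 residual degrees of freedom, which by itself raises p. The aliases Lsh and Gp130 were left out because each matched only another gene. Groups, contrasts, lists, all but 3 of the alternatives and the rule for named genes were fixed before the data were examined. By that rule, the text names Dnmt3l and Rhox5, the 12 largest rises and 12 largest falls among genes called over the 3 hairpins with the same sign in each, up to 4 members of each list with the smallest adjusted p, the 5 largest rises and falls with each hairpin, the 10 largest changes among genes called with every hairpin, and the 10 called genes with the largest range among hairpin groups. Symbols of clones and predicted genes were passed over. Other members of a list are named where they describe that list, and were chosen after their values were seen.

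The scripts were tested on simulated data with known changes before use. In a simulation of 10930 genes with 100 genes changed by each size, the comparison of the 3 hairpins with shGFP recovered 88% of changes of 0.5 and 100% of changes of 1 on the log2 scale, with 5 false calls. The comparisons of single hairpins recovered 74% to 76% of changes of 0.5 and 99% to 100% of changes of 1, with 6 to 11 false calls. The simulated arrays varied independently by the spread between duplicates, without variation between cultures or between hairpins. These figures therefore do not cover such variation. Changes shared between comparisons against the same shGFP arrays were set beside 100 simulations of unchanged groups, drawn with the same spread. The alternatives covered background correction, normalization, the authors' values, the filter on dim probes, the probe per gene, a replicate block, array weights, the prior, leaving out each array, simpler and blocked models of the hairpins, thresholds and the list test. A slide block was not run, since no source gives the slide.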

Results

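Gene expression was measured on 8 arrays of E14 mouse embryonic stem cells that carried a control hairpin against GFP (shGFP) or 1 of 3 hairpins against Dnmt3l (shDnmt3L1, shDnmt3L2 and shDnmt3L3), with 2 arrays per group. Per the series title, the study asks how Dnmt3L-dependent DNA methylation bears on the differentiation of stem cells toward germ cells. The median signal per array lay between 96.1 and 104, and 18111 to 19241 of 45281 probes (40.0% to 42.5%) were detected above the negative controls. After normalization the arrays of a group correlated at 0.996 to 0.997 across the genes tested, arrays of different hairpin groups at 0.977 to 0.993, and shGFP with hairpin arrays at 0.968 to 0.982. In a principal component analysis the first component, with 48.3% of the variance, placed shGFP at 1 end and shDnmt3L3 at the other. The second component, with 33.4%, set shDnmt3L1 and shDnmt3L2 apart from shGFP and shDnmt3L3. Genes are not independent replicates, and 2 arrays per group limit the precision of every value below.

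Dnmt3l itself, the target of the hairpins, was lower on each of the 6 hairpin arrays than on both shGFP arrays. Its normalized log2 intensity was 11.87 and 11.97 with shGFP, 10.51 and 10.45 with shDnmt3L1, 10.73 and 10.84 with shDnmt3L2, and 9.34 and 9.19 with shDnmt3L3. This left 36.8%, 45.4% and 15.8% of the shGFP level with shDnmt3L1, shDnmt3L2 and shDnmt3L3, and a second Dnmt3l probe gave 38.1%, 41.7% and 13.9%. Over the 3 hairpins Dnmt3l fell by 1.75 ± 0.07 (SE) on the log2 scale (limma, adjusted p = 3.21e-06). The hairpin groups also differed from each other in Dnmt3l (F test, adjusted p = 1.57e-05), in the order shDnmt3L3 lowest, then shDnmt3L1, then shDnmt3L2. That F test does not set shDnmt3L1 against shDnmt3L2 alone. These 2 groups lay close in the second probe, with log2 changes of -1.39 ± 0.09 and -1.26 ± 0.09 (SE) against shGFP.

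The comparison of the 3 hairpin groups with shGFP asks which genes changed after knockdown of Dnmt3l. The largest falls were in 3 homeobox genes of the X-linked Rhox cluster, which is active in reproductive tissues and placenta: Rhox6 (-2.77 ± 0.13, log2 ± SE here and below), Rhox9 (-2.57 ± 0.08) and Rhox5 (-2.30 ± 0.07). Nanos3, an RNA-binding protein that germ cell precursors need to survive, was detected with shGFP and on none of the 6 hairpin arrays, a fall of at least 3.30-fold. Among the largest rises were Adssl1, an enzyme of adenine nucleotide synthesis in muscle (1.87 ± 0.07), Acta2, smooth muscle actin (1.68 ± 0.08), and Serpinh1, the chaperone of collagen in the endoplasmic reticulum (1.59 ± 0.07). All of these passed limma's test at adjusted p of 3.39e-06 or less.

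**Figure D1:**
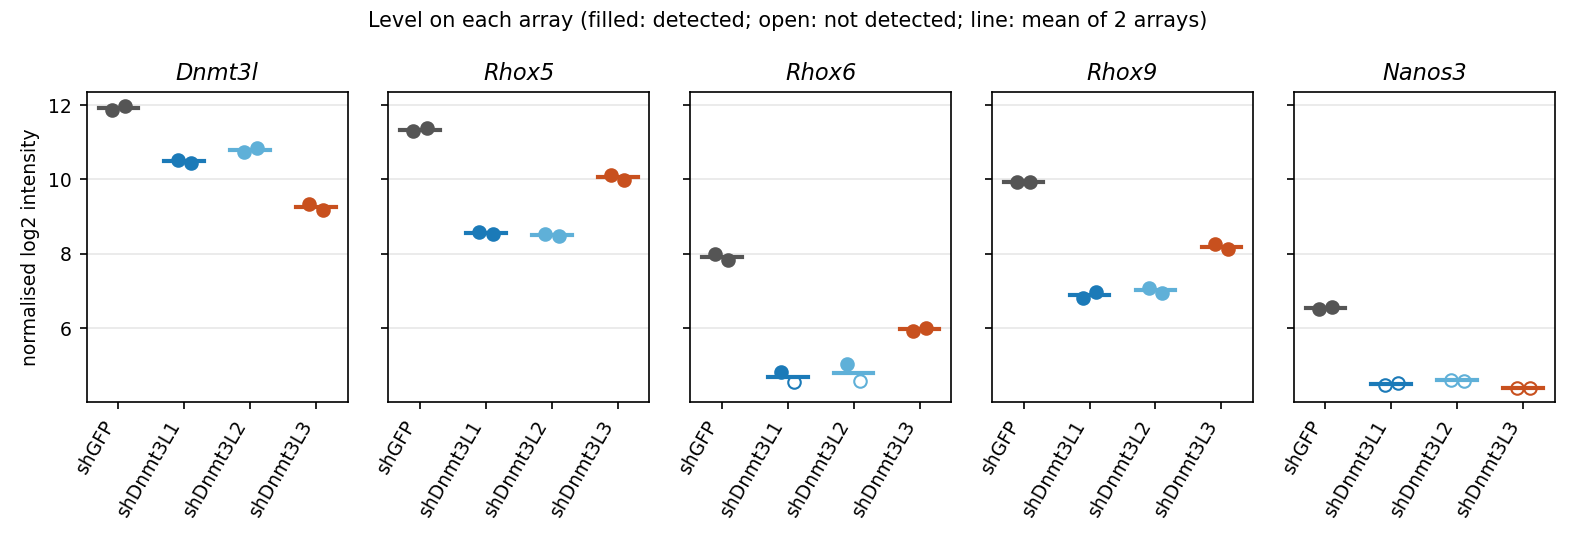
Normalized log2 intensity (vertical axis) of Dnmt3l, Rhox5, Rhox6, Rhox9 and Nanos3 on each of the 8 arrays, by group (horizontal axis); filled points were detected, open points were not, and each line is the mean of 2 arrays. Dnmt3l was lowest with shDnmt3L3 (9.34 and 9.19), while Rhox5, Rhox6 and Rhox9 were lowest with shDnmt3L1 and shDnmt3L2.

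The other rises named by the rule were Macrod1, a mono-ADP-ribosyl hydrolase (1.79), Rab11fip5, an effector of the recycling endosome GTPase Rab11 (1.75), Pramel20 (1.63, detected on 1 of 2 shGFP arrays), Dhrs7, a short-chain dehydrogenase (1.63), Zfhx3, a transcription factor with zinc fingers and homeodomains (1.62), Add3, a protein of the membrane skeleton (1.62), Prr15l (1.59) and Rnf130 (1.53). Cox6b2, a testis form of a cytochrome c oxidase subunit, had the largest value (3.15 ± 0.86, adjusted p = 0.0137), but its shGFP arrays read 8.51 and 4.17 and it was not detected on the second. Without shGFP replicate 1 the change in Cox6b2 was 5.33, and without shGFP replicate 2 it was 0.97. Cox6b2 did not pass with shDnmt3L2 (2.95). The remaining falls were in Spink1, a secreted protease inhibitor (-2.18), Msc, a helix-loop-helix repressor (-2.05), Gbp2, an interferon-induced GTPase (-1.81), Gbx2, a homeobox gene downstream of LIF (-1.58), and Dtx3l, a ubiquitin ligase induced by interferon (-1.54). Rgcc, a cell cycle regulator, was not detected with shDnmt3L2 and fell at least 3.03-fold over the 3 hairpins but did not pass with shDnmt3L3 (-0.24), and Gbp2b, a paralog of Gbp2, was not detected with shDnmt3L3 and fell at least 3.01-fold. Rhox6 was detected on 1 of 2 arrays with shDnmt3L1 and on 1 of 2 with shDnmt3L2.

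Of the gene lists, the Rhox cluster, targets of the tumour suppressor p53 and genes of the interferon response had the smallest camera p. In the Rhox cluster, 4 of 5 measured members fell and none rose, with Rhox13 at -0.68 ± 0.08 as the smallest called fall, while Rhox10 (-0.12) did not pass except with shDnmt3L3 (-0.43). Among p53 targets, 15 of 25 rose and 2 fell. The risers included Ephx1, an epoxide hydrolase (1.23 ± 0.08), Ddit4l, an inhibitor of mTOR (1.02 ± 0.06), Dcxr, a carbonyl reductase (0.96 ± 0.06), Cdkn1a, the cyclin-dependent kinase inhibitor p21 (0.71 ± 0.06), and the death receptor Fas, which was not detected with shGFP and rose at least 1.70-fold. In the interferon response, 14 of 23 fell and 1 rose. The fallers included Gbp2, Oas1g, an oligoadenylate synthetase (-1.11 ± 0.08), Ddx58, the RNA sensor RIG-I (-0.84 ± 0.06), and Rsad2, an antiviral enzyme that was detected on no hairpin array (at least 1.22-fold lower), while Isg15 (0.05) and Stat2 (0.09) did not pass. Each of these 3 lists had a camera adjusted p of 0.00052 over the 25 lists. With an estimated correlation the adjusted p was 0.164 for the Rhox cluster, 0.134 for p53 targets and 0.134 for the interferon response.

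Glycolysis, two-cell-like genes and endoderm markers were also higher than the other genes as lists. In glycolysis 11 of 18 rose and 1 fell (11 and 2 adjusted over the list alone), with Hk1, a hexokinase (1.15 ± 0.09), Eno2, an enolase (0.73 ± 0.07), and the phosphofructokinases Pfkl (0.52 ± 0.07) and Pfkm (0.49 ± 0.07) among the risers, while Gapdh (0.07) and Ldha (-0.06) did not pass. Of 8 two-cell-like genes, which mark the rare cells of a culture that resemble the early cleavage embryo, 5 rose and 1 fell. Zscan4c (1.36 ± 0.08), Tmem92 (1.31 ± 0.10, detected on 1 of 2 shGFP arrays), Tcstv1 (0.85 ± 0.09) and Tcstv3 (0.83 ± 0.06) rose, of which Tcstv1 did not pass with shDnmt3L3 (0.26). Of 18 primitive and definitive endoderm markers, 12 rose and 5 fell (13 and 5 adjusted over the list alone). The basement membrane genes Col4a1 (1.25 ± 0.07), Col4a2 (1.16 ± 0.07) and Lama1 (0.60 ± 0.06) and the adaptor Dab2 (0.97 ± 0.10) were among the rises, although Lama1 did not pass with shDnmt3L1 (-0.13) nor Dab2 with shDnmt3L3 (0.07), Sox7 (-0.22, with -0.0003 for shDnmt3L3) and Sparc (-0.30) fell, and Gata4, Gata6 and Sox17 were not among the measured members. The camera adjusted p was 0.0187 for glycolysis, 0.0438 for two-cell-like genes and 0.0474 for endoderm markers. The adjusted p with an estimated correlation was 0.203, 0.30 and 0.260 in the same order, so that 0 of the 6 list calls held with it. The estimates were -0.02, 0.058 and -0.0412 in that order. They were 0.0437 for the Rhox cluster, -0.014 for p53 targets and -0.0328 for the interferon response. For estimates below the preset 0.01, the higher p does not come from the correlation. With single hairpins the endoderm list was not called (0.0577, 0.122 and 0.0806 for shDnmt3L1, shDnmt3L2 and shDnmt3L3), glycolysis was not called with shDnmt3L2 (0.125) and two-cell-like genes were not called with shDnmt3L3 (0.386). Across 25 alternatives, 3 of them chosen after the data were seen, the endoderm call was lost under 11, the two-cell-like call under 6 and the glycolysis call under 2.

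The lists closest to germ cells and DNA methylation moved in both directions and were not called. Of 20 primordial germ cell genes, which include Rhox5, Rhox6 and Rhox9, 7 rose and 7 fell (camera adjusted p = 0.265). Dppa3, a maternal factor that marks germ cell precursors (0.39), Prdm1 (0.26) and Tfap2c (0.23), regulators of germ cell specification, were among the risers, and Dazl (-0.13), Ddx4 (-0.02) and Kit (-0.15) did not pass. Dazl fell with shDnmt3L3 (-0.36) and Kit with shDnmt3L1 (-0.49). The hairpins differed in these 3 risers: Dppa3 rose with shDnmt3L1 and shDnmt3L2 (0.87 and 0.69) and fell with shDnmt3L3 (-0.39). Prdm1 passed with the first pair (0.33 and 0.48) and had -0.01 with shDnmt3L3, while Tfap2c passed with shDnmt3L3 (0.62) and had -0.06 and 0.14 with shDnmt3L1 and shDnmt3L2. Of 19 germline genes silenced by DNA methylation in somatic cells, 8 rose and 4 fell (0.513), with a median of -0.0045, a mean of 0.15 and a test direction up. The cohesin subunit Smc1b (1.34 ± 0.06), the meiotic gene Hormad2 (1.01 ± 0.08), Tuba3a (0.67 ± 0.08) and Tdrkh (0.56 ± 0.06) rose. Of 29 imprinted genes, 11 rose and 4 fell (0.173), led by the growth factor Igf2 (1.31 ± 0.06), Slc22a18 (0.71 ± 0.07, with -0.13 in another probe and 0.11, not passing, for shDnmt3L2), Cd81 (0.66 ± 0.06) and Phlda2 (0.65 ± 0.07). In the DNA methylation machinery, 3 of 17 rose and 8 fell (4 and 8 adjusted over the list alone, 0.265). Uhrf2 (0.60 ± 0.06) and the dioxygenase Tet1 (0.46 ± 0.08) rose, Gadd45a (-0.49 ± 0.07) and the glycosylase Tdg (-0.48) fell, and the methyltransferases Dnmt1 (0.05) and Dnmt3b (0.19) did not pass. Dnmt3b rose with shDnmt3L1 and shDnmt3L2 (0.80 and 0.78) and fell with shDnmt3L3. Tet1 did not pass with shDnmt3L1 (0.20), nor Tdg with shDnmt3L3 (-0.19).

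Pluripotency genes moved in both directions. Of 27 pluripotency genes, 8 rose and 5 fell (camera adjusted p = 0.815). Lefty1, an inhibitor of NODAL (0.79 ± 0.06), and Fgf4 (0.67 ± 0.08) rose, Gbx2 and Dppa2 (-0.71 ± 0.11) fell, and Nanog (-0.01), Sox2 (-0.15) and Pou5f1 (0.0035) did not pass. With single hairpins Pou5f1 rose with shDnmt3L2 (0.24) and fell with shDnmt3L3 (-0.40), Sox2 fell with shDnmt3L2 (-0.32), and Tfcp2l1 (-0.66), Klf4 (-0.48) and Esrrb (-0.28) fell with shDnmt3L1. Tfcp2l1 (0.35) and Esrrb (0.24) rose with shDnmt3L3. Lefty1 rose with shDnmt3L1 and shDnmt3L2 (1.30 and 1.13) and had -0.07 with shDnmt3L3. Of 14 primed epiblast genes, 3 rose and 3 fell (0.877, with a mean of 0.03 and a test direction down). Cldn6, a tight junction protein (0.79 ± 0.07), and Sox4 (0.59 ± 0.09) rose, and Lef1 and Fgf5, not detected with shDnmt3L3, fell at least 1.62-fold and at least 1.17-fold. Fgf5 was not lower with the other hairpins: it rose with shDnmt3L2 (0.30) and did not pass with shDnmt3L1 (0.14), and its value was 0.219 without the shDnmt3L3 arrays. Among the other lineages, 4 mesoderm genes rose and 2 fell of 10 (0.440, Bmp4 -0.95 ± 0.09 and Evx1 at least 1.40-fold lower), 5 neuroectoderm genes rose and 1 fell of 11 (0.225, Gli3 0.64 ± 0.08, Dll1 0.60 ± 0.09 and Olig1 at least 1.34-fold higher). Bmp4 (-0.19) and Gli3 (-0.10) did not pass with shDnmt3L3, nor Olig1 with shDnmt3L2 (0.22). Gata2, detected with shDnmt3L3 and in no other group, and Lhx1, detected with shDnmt3L1 and on 1 array with shDnmt3L2, are also on the mesoderm list and rose at least 1.11-fold and at least 1.02-fold. Of 14 trophectoderm genes 8 rose and 2 fell (9 and 2 adjusted over the list alone, 0.144). Krt7 (1.29 ± 0.11, detected on 1 of 2 shGFP arrays) and Plac8 (0.73 ± 0.06) rose and Rhox6 and Rhox9 fell, so that the median was 0.23 and the mean -0.03, with a test direction up. Of 12 fibroblast and feeder cell markers 5 rose and 1 fell (0.136), with Acta2, Mmp2 (1.45 ± 0.07), Thy1 (0.97 ± 0.07) and Col5a1 (0.93 ± 0.07) among the risers and Vim (0.02, with -0.44 for shDnmt3L1 and 0.35 for shDnmt3L3, both called) not passing.

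Signalling and general lists were not called over the 3 hairpins either. Of 14 ERK pathway targets 7 fell and 1 rose (camera adjusted p = 0.0786), with Spry4 (-1.27 ± 0.11), Etv4 (-0.98 ± 0.10), Egr1 (-0.96 ± 0.07) and Dusp6 (-0.85 ± 0.08) among the falls, of which Etv4 did not pass with shDnmt3L3 (-0.03). The ERK list was called under 6 of 25 alternatives and not under the other 19. Of 28 genes of the unfolded protein and integrated stress response 11 fell and 2 rose (0.144), with Chac1 (-0.86 ± 0.07), Atf5 (-0.78 ± 0.08) and Slc7a3 (-0.48 ± 0.07) lower and Ddit4 (0.54 ± 0.07) higher. Slc7a3 passed with shDnmt3L3 (-1.54) and had -0.11 and 0.21 with shDnmt3L1 and shDnmt3L2, and neither Chac1 (-0.17) nor Ddit4 (0.11) passed with shDnmt3L2. Of 19 LIF STAT3 targets 8 fell and 4 rose (0.225), with Jund (1.01 ± 0.10) and Cish (0.94 ± 0.07) higher and Mras (-0.40 ± 0.06) lower. Mras passed with shDnmt3L1 (-1.34) and had 0.03 and 0.12 with shDnmt3L2 and shDnmt3L3, and its value was 0.0754 without the shDnmt3L1 arrays. Of 9 Wnt targets 3 fell and 1 rose (0.354, median 0.02, mean -0.22 and a test direction down), with Sp5, not detected with shDnmt3L3, at least 2.54-fold lower, Notum (-0.70 ± 0.08) lower and Tnfrsf19 (0.55 ± 0.10) higher. Notum did not pass with shDnmt3L2 (-0.05). Of 37 cell cycle genes 12 fell and 5 rose (0.225), with Rrm2 (-0.76 ± 0.07) and Pcna (-0.65 ± 0.07) lower and E2f1 (0.64 ± 0.07) higher. Of 26 Polycomb components 5 rose and 5 fell (0.880), with Phc2 (0.51 ± 0.08) and Phc1 (0.42 ± 0.06) higher and Phf19 (-0.69 ± 0.07) and Eed (-0.49 ± 0.07) lower. The other detected probes of Phc1 gave -0.16 and 0.15, and neither passed. Phc1 did not pass with shDnmt3L3 (0.01), nor Eed with shDnmt3L2 (-0.14). Of 16 bivalent homeobox genes 3 rose and 4 fell (0.962, median 0.15, mean -0.04 and a test direction up), with En1 (-1.46 ± 0.07) and Meis1 (-0.47 ± 0.08) lower and Irx3 (0.49 ± 0.09, not passing with shDnmt3L2 at 0.18) higher. Of 51 cytosolic ribosomal proteins 5 rose and 1 fell (3 and 1 adjusted over the list alone, 0.694), with Rpl22 (0.83 ± 0.06), Rps15 (0.50 ± 0.06) and Rpl29 (0.28 ± 0.07, with -0.25 in another probe) higher and Rpl21 (-0.37 ± 0.08, not passing with shDnmt3L2 at -0.26) lower. Of 15 housekeeping genes 5 rose and 3 fell (0.551), with B2m (0.71 ± 0.06), Eif4a2 (0.35 ± 0.06) and Gusb (0.30 ± 0.07) higher and Tfrc (-0.27 ± 0.06) lower, and the test direction, up, turned down with median scaling. Gusb (0.0049) and Tfrc (-0.20) did not pass with shDnmt3L3, nor Eif4a2 with shDnmt3L2 (0.18). For every list whose second count is not given, the counts adjusted over the list alone were the same.

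For Dnmt3l knockdown against shGFP, 5707 of 10930 genes (52.2%) were called over the 3 hairpins with limma, 3004 higher and 2703 lower, of which 846 and 515 changed at least 1.5-fold. Higher genes made up 52.6% of the calls, and 63.8% with median scaling in place of quantile normalization. With the hairpin as a random block in limma, the calls fell to 323 (224 higher and 99 lower), and Dnmt3l itself had an adjusted p of 0.052. This model takes 1 correlation between the arrays of a group for all genes (consensus correlation 0.691). Its degrees of freedom still count arrays rather than hairpins, so it may call too many genes. A model of 2 groups, 6 hairpin arrays against 2 shGFP arrays, called 2377.

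**Figure D2:**
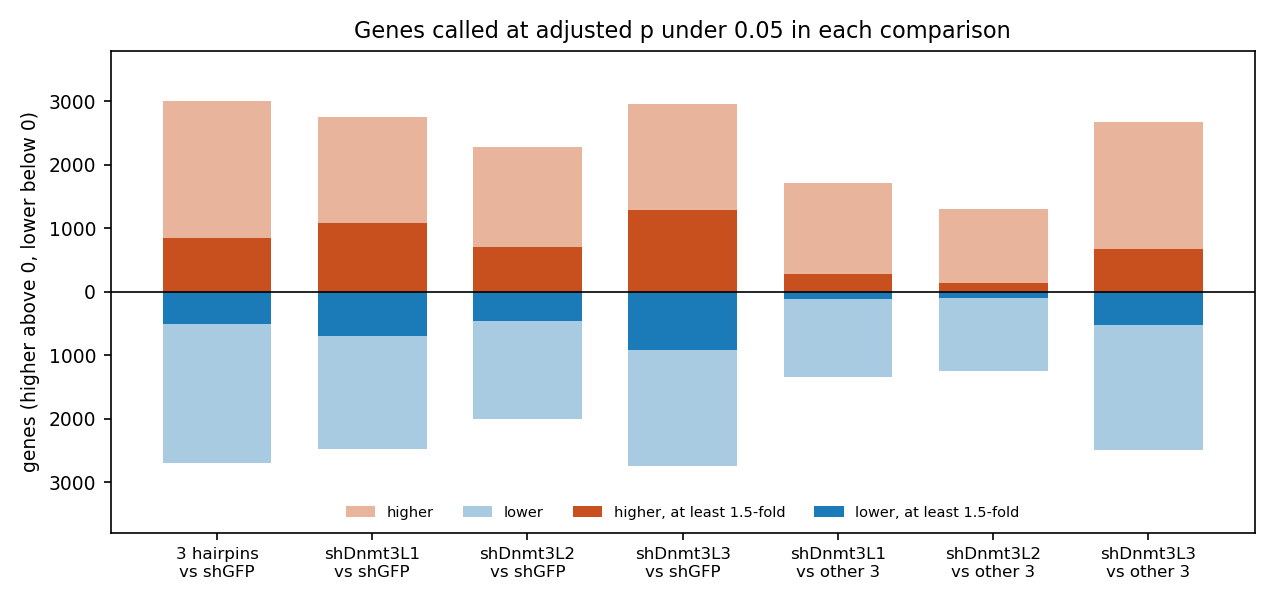
Number of genes called at an adjusted p under 0.05 (vertical axis, higher genes above 0 and lower genes below) in each comparison (horizontal axis); the dark part of each bar is the genes that changed at least 1.5-fold. The comparison of the 3 hairpins with shGFP called 5707 genes and that of shDnmt3L3 with the other 3 groups 5162.

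With shDnmt3L1, which left 36.8% of Dnmt3l, the largest falls were in Rhox6 (-3.24 ± 0.15, with 1 of 2 arrays below detection), Rhox9 (-3.05 ± 0.09), Spink1 (-2.95 ± 0.09), Rhox5 (-2.79 ± 0.08) and Msc (-2.72 ± 0.08). The largest rises beside Cox6b2 (3.18 ± 1.05, detected on 1 of 2 shGFP arrays) were in Pdzk1, a scaffold of membrane transporters (2.36 ± 0.09), Acta2 (2.33 ± 0.09), Zfhx3 (2.00 ± 0.10) and Pramel20 (1.95 ± 0.13). Targets of LIF and STAT3, the pathway that maintains self-renewal, were lower as a list (camera adjusted p = 0.00231, and adjusted p = 0.121 with an estimated correlation): 13 of 19 fell and 2 rose, with Gbx2 (-2.29 ± 0.12), the feedback inhibitor Socs3 (-1.37 ± 0.07), Mras (-1.34 ± 0.07) and Bcl3 (-1.31) among the falls. Of 14 ERK pathway targets 8 fell and 3 rose (0.0425, and adjusted p = 0.175 with an estimated correlation), with Etv4 at -2.01 ± 0.12 and Spry4 at -2.0 ± 0.13. Of 28 stress response genes 14 fell and 2 rose (14 and 3 adjusted over the list alone; camera adjusted p = 0.0271, and adjusted p = 0.149 with an estimated correlation), with the glutathione-degrading enzyme Chac1 at -1.85 ± 0.08 and Atf5 at -1.18 ± 0.10.

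The camera adjusted p with shDnmt3L1 follows for the other lists called. Primed epiblast genes were higher (9 rose and 1 fell of 14, 0.00452), as were p53 targets (15 and 1 of 25, 0.00299), glycolysis (9 and 0 of 18, 0.0113) and two-cell-like genes (6 and 1 of 8, 0.0130). With an estimated correlation the adjusted p was 0.121, 0.121, 0.132 and 0.175 in the same order. The interferon response (1 rose and 13 fell of 23, 0.00231) and the Rhox cluster (0 and 4 of 5, 0.00219) were lower, each with an adjusted p of 0.121 with an estimated correlation. In total 5231 genes were called, 2757 higher and 2474 lower, of which 1089 and 697 changed at least 1.5-fold.

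With shDnmt3L2, which left 45.4% of Dnmt3l, Rhox6 (-3.11 ± 0.15, with 1 of 2 arrays below detection), Rhox9 (-2.92 ± 0.09) and Rhox5 (-2.83 ± 0.08) again had the largest falls, with Rgcc (at least 5.03-fold) and Nanos3 (at least 3.28-fold), both not detected there. The largest rises were in Zfhx3 (1.90 ± 0.10), Acta2 (1.87 ± 0.09), Pramel20 (1.65 ± 0.13), the decoy receptor Tnfrsf22 (1.64 ± 0.07) and Add3 (1.55 ± 0.08). The used probe of Tnfrsf22 gave 1.15 over the 3 hairpins, while none of its 3 other detected probes passed (0.03, 0.24 and -0.02). Primed epiblast genes were higher (11 rose and 1 fell of 14, camera adjusted p = 0.00297), and so were pluripotency genes (11 and 3 of 27, or 12 and 3 adjusted over the list alone, 0.0327), p53 targets (15 and 3 of 25, or 17 and 4 adjusted over the list alone, 0.00424) and two-cell-like genes (6 and 1 of 8, 0.00428). With an estimated correlation the adjusted p was 0.130, 0.381, 0.130 and 0.219 in the same order. The interferon response (0 rose and 10 fell of 23, or 0 and 11 adjusted over the list alone, 0.00297) and the Rhox cluster (0 and 4 of 5, 0.00207) were lower, each with an adjusted p of 0.130 with an estimated correlation. In total 4280 genes were called, 2275 higher and 2005 lower, of which 698 and 463 changed at least 1.5-fold.

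With shDnmt3L3, which left 15.8% of Dnmt3l, primed epiblast genes were lower (camera adjusted p = 6.46e-05, and adjusted p = 0.0936 with an estimated correlation). Of 14, 12 fell and 2 rose: the transcription factors Zic2 (-1.63), Otx2 (-1.32) and Pou3f1 (-1.08) and the methyltransferase Dnmt3b (-1.0) fell, Lef1 and Fgf5, both not detected there, fell at least 2.44-fold and at least 2.20-fold, and Sox4 (0.35 ± 0.11) and Cldn6 (0.32 ± 0.09) rose. The largest rises beside Cox6b2 (3.32 ± 1.05, detected on 1 of 2 shGFP arrays) were in the cross-linking enzyme Tgm2 (3.11 ± 0.08), Adssl1 (2.53 ± 0.09), Macrod1 (2.5 ± 0.10) and Rab3il1, which was not detected with shGFP (at least 5.69-fold). The largest falls were in Gbp2 (-2.77 ± 0.15, detected on 1 of 2 arrays), Spink1 (-2.67 ± 0.09), Dnmt3l (-2.66 ± 0.09), and Samd9l, an interferon-induced gene, and Cabs1, a sperm protein, which were not detected there (at least 5.10-fold and at least 5.76-fold).

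The camera adjusted p with shDnmt3L3 follows for the other lists. Targets of p53 were higher (17 rose and 2 fell of 25, 7.15e-05, Ephx1 1.76 ± 0.09 and Cdkn1a 1.23 ± 0.08), as was glycolysis (11 and 0 of 18, 0.0188, Hk1 1.94 ± 0.11), with an adjusted p of 0.0936 and 0.175 with an estimated correlation. The Rhox cluster (0 rose and 5 fell of 5, 0.00105) and the interferon response (1 and 14 of 23, 0.00105) were lower, with an adjusted p of 0.149 and 0.118 with an estimated correlation. Two-cell-like genes were not called (0.386). In total 5700 genes were called, 2958 higher and 2742 lower, of which 1296 and 926 changed at least 1.5-fold.

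**Figure D3:**
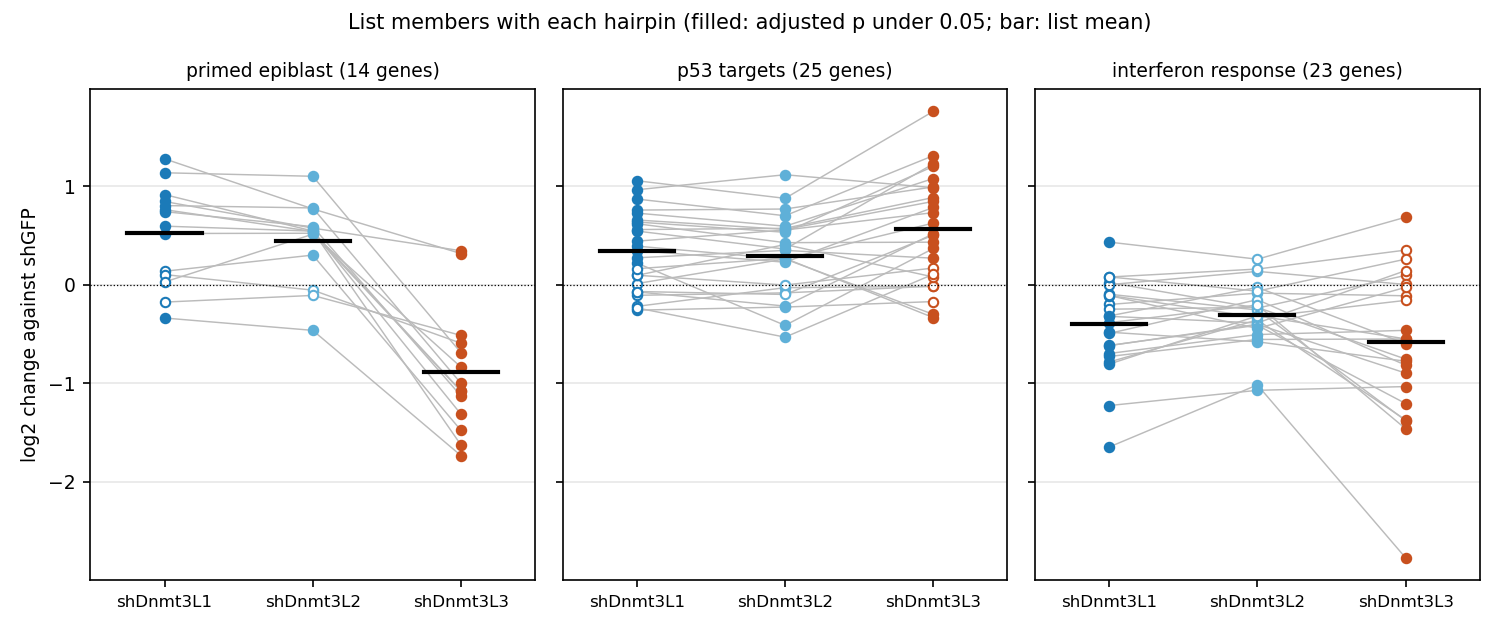
Log2 change against shGFP (vertical axis) of each measured member of 3 gene lists with each hairpin (horizontal axis); filled points had an adjusted p under 0.05, lines join a gene, and the black bar is the list mean. Primed epiblast genes had list means of 0.53 and 0.44 with shDnmt3L1 and shDnmt3L2 and -0.89 with shDnmt3L3, while p53 targets were above 0 and interferon response genes below 0 with each hairpin.

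Genes called with every hairpin address whether a change depends on 1 hairpin sequence. The 10 largest among them were the falls of Rhox6, Rhox9, Rhox5, Spink1, Msc, Nanos3 and Gbp2 and the rises of Adssl1, Macrod1 and Rab11fip5. Nanos3 fell at least 3.35-fold, 3.28-fold and 3.27-fold with shDnmt3L1, shDnmt3L2 and shDnmt3L3, and no difference among the hairpins was called for it (F test, adjusted p = 0.119), with all hairpin arrays below detection. Rab11fip5 rose by 1.60, 1.48 and 2.17, and Adssl1 by 1.80, 1.29 and 2.53, in the same order.

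Of 7628 genes called with at least 1 hairpin, 2406 were called with all 3 in the same direction, 1306 higher and 1100 lower. Ranking the 3 hairpins by the size of the change, the order shDnmt3L3, shDnmt3L1, shDnmt3L2, which is the order of Dnmt3l loss, held for 804 of the 2406 genes (33.4%). The order shDnmt3L1, shDnmt3L2, shDnmt3L3, with the smallest change at the lowest Dnmt3l, held for 495 (20.6%). Equal shares would give 16.7% each, but shDnmt3L3 had the most changes of at least 1.5-fold overall. Across genes, changes correlated at 0.869 between shDnmt3L1 and shDnmt3L2, 0.670 between shDnmt3L1 and shDnmt3L3 and 0.581 between shDnmt3L2 and shDnmt3L3, where 100 simulations of unchanged groups gave 0.50, 0.499 and 0.50. The covariances were 0.146, 0.152 and 0.110, against a simulated 0.00593, 0.00591 and 0.00593. Genes are not independent replicates. With 1 shGFP array given to each hairpin of a pair, a check chosen after the data were seen, the correlations were 0.775 and 0.778, 0.606 and 0.610, and 0.510 and 0.512 for the same pairs, and the covariances 0.137 and 0.137, 0.143 and 0.143, and 0.101 and 0.102. A difference common to both shGFP arrays stays in all of these values.

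The hairpins also differed from each other. Tgm2 rose by 0.54, 0.81 and 3.11 with shDnmt3L1, shDnmt3L2 and shDnmt3L3, and Kdelr3, a retrieval receptor of the endoplasmic reticulum, had values of -0.15, 0.36 and 2.47. The peptidase Dpp4 rose with the first pair (0.85 and 0.65) and fell with shDnmt3L3 (-1.78), and the stress-induced factor Ddit3 fell with the first pair (-0.87 and -0.67) and rose with shDnmt3L3 (1.42). Socs3 fell with shDnmt3L1 (-1.37) and rose with shDnmt3L2 (0.30) and shDnmt3L3 (0.96). Lpar4, a receptor for lysophosphatidic acid (-0.13, -0.12 and -2.41), En1 (-1.59, -0.26 and -2.53), Samd9l and Cabs1 were lowest with shDnmt3L3, and Rgcc (-2.22 with shDnmt3L1 and -0.24 with shDnmt3L3) was lowest with shDnmt3L2.

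The F test of equal means among the 3 hairpin groups, which does not use shGFP, called 4899 genes (44.8%), and 1860 of them had a range of at least 1.5-fold. Its adjusted p for the 10 genes above lay between 1.58e-06 for Tgm2 and 9.35e-06 for Rgcc. For 384 genes the calls against shGFP had opposite signs with different hairpins. All 384 also passed the F test, which opposite calls against a shared control make nearly certain in advance. Of these, 110 rose with shDnmt3L1 and shDnmt3L2 and fell with shDnmt3L3, and 53 did the reverse. All 14 primed epiblast genes were lower with shDnmt3L3 than with the mean of shDnmt3L1 and shDnmt3L2, by -1.37 on average (camera adjusted p = 2.94e-11, and 0.0409 with an estimated correlation), a contrast chosen after the values were seen.

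Each hairpin group was also set against the mean of the other 3 groups. A gene that changed in only 1 of those other groups can be called there too. A call therefore does not show that the hairpin group itself stood apart. Beside the 5707 genes called between shGFP and the hairpin groups, 3059 were called for shDnmt3L1 (1717 higher and 1342 lower). The counts were 2545 for shDnmt3L2 (1303 and 1242) and 5162 for shDnmt3L3 (2669 and 2493). Changes of at least 1.5-fold numbered 402, 227 and 1206 in these comparisons. Without 1 of its own arrays the count was 1370 or 1390 for shDnmt3L1 against the other 3 groups and 969 or 1006 for shDnmt3L2 against the other 3 groups, where the lone array is assumed to vary like the other groups.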

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

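All tests of an explanation in this part were chosen after the results they bear on had been seen, except the test of background correction and normalization for the primed epiblast genes.

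The hairpin groups differed from each other in 4899 genes by the F test, in 100 of the 118 named genes, some of which were chosen for such differences, and in 384 genes that were called higher with 1 hairpin and lower with another. As lists, with shDnmt3L3 set against the mean of the other hairpins, primed epiblast genes differed by -1.37, two-cell-like genes by -0.58 (camera adjusted p = 0.00559, and 0.313 with an estimated correlation), p53 targets by 0.25 (0.00658, and 0.252) and Wnt targets by -0.55 (0.00926, and 0.319). Outside the named genes, 1301 detected probes without a single gene name were called over the 3 hairpins, 626 higher and 675 lower.

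Primed epiblast genes were higher with shDnmt3L1 and shDnmt3L2 (list means 0.53 and 0.44) and lower with shDnmt3L3 (-0.89). A response that grows in 1 direction with the loss of Dnmt3l is argued against as the whole cause. The list mean with shDnmt3L3, which had the lowest Dnmt3l, minus that with shDnmt3L1 was -1.41 (SD between arrays 0.0135, a spread that may be technical). Such a response together with an effect of shDnmt3L3 on other transcripts is not argued against. Background correction or normalization as the whole cause is argued against too: under 5 other settings shDnmt3L3 minus the mean of the other hairpins stayed at -0.773 or below. A candidate explanation is an effect of 1 or more hairpins on other transcripts, and another is a response to Dnmt3l that changes direction with its level. Neither was tested: the hairpin sequences are not given in the sources used here, and each level of Dnmt3l comes from a different hairpin.

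Rhox5, Rhox6 and Rhox9 fell less with shDnmt3L3 than with the other hairpins, although Dnmt3l was lowest there. Their mean was higher by 1.37 with shDnmt3L3 than with shDnmt3L1 (SD between arrays of a group 0.0843, a spread that may be technical). For these genes, a fall that only grows with the loss of Dnmt3l is argued against as the whole cause of the differences among hairpins. A response that changes direction with the level of Dnmt3l is not argued against and was not tested. A fall that follows depth together with an effect of a hairpin on other transcripts is not argued against. Each level of Dnmt3l comes from a different hairpin. Near background the scale shortens the falls of the lowest readings, here Rhox6 with shDnmt3L1 and shDnmt3L2 (-0.26 to 0.22 from the lowest detected level), which makes the difference from shDnmt3L3 smaller, not larger. Hairpin-specific effects stay open and untested.

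Targets of p53 were higher and interferon response genes lower with every hairpin, with list means of 0.34, 0.29 and 0.56 and of -0.40, -0.31 and -0.58 for shDnmt3L1, shDnmt3L2 and shDnmt3L3. Both orders follow the level of Dnmt3l, with the smaller step 0.0492 for p53 targets (SD 0.00913) and 0.0953 for the interferon response (SD 0.0280). That step lies between shDnmt3L1 and shDnmt3L2, whose Dnmt3l levels were close in the second probe (38.1% and 41.7% of shGFP). The spread may be technical. A response graded by Dnmt3l would give this order, but the order is not particular to these lists. Genes that changed at least 1.5-fold numbered 1161, 1786 and 2222 with shDnmt3L2, shDnmt3L1 and shDnmt3L3. Across all genes, shDnmt3L3 minus shDnmt3L1 correlated at -0.246 with shDnmt3L2 minus shGFP, where a grading shared by all genes would give a positive value. The order of 3 points was seen first, and chance alone gives a set order 1 time in 6. A change in the shGFP arrays cannot be told apart for the part of the change that all hairpins share, because the design has a single control hairpin. The smallest fitted change was 0.290 for p53 targets and 0.308 for the interferon response. It bounds that part only if no hairpin moved the list the other way, which the design cannot show. An effect of all 3 hairpins on other transcripts was not tested.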

How the results depend on the processing

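The alternatives without both arrays of a hairpin were chosen after seeing the data. All others were set before the data were examined. Of 3444 such repeats of a gene's test, 3285 kept direction and side of the threshold, 152 lost the call and 7 changed sign. Of 550 repeats of a list test, 491 kept both, 18 lost the call, 20 gained one and 21 changed direction, and 204 of 226 counts stayed within 1.5 times. Without the arrays of a hairpin, 336 of 354 gene tests, 62 of 75 list tests and 6 of 6 counts were the same. Stricter thresholds lower a count by construction. For every other value given here the cause was not tested. Dim genes are limited by their signal over background, since 40.0% to 42.5% of probes were detected.

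For Dnmt3l knockdown against shGFP, 2 groups of 6 and 2 arrays gave 2377 genes, the hairpin as random block 323 and a change of at least 1.5-fold 1361. With the random block Dnmt3l, pooled knockdown, kept its change of -1.75 at an adjusted p of 0.052. With a change of at least 1.5-fold, shDnmt3L1 against shGFP gave 1786, shDnmt3L2 against shGFP 1161, shDnmt3L3 against shGFP 2222, shDnmt3L1 against the other 3 groups 402, shDnmt3L2 against the other 3 groups 227 and shDnmt3L3 against the other 3 groups 1206. The count of genes called in all 3 hairpins was then 526 and that of the difference among the 3 hairpins 1860. At an adjusted p under 0.01 the counts were 2589 for shDnmt3L2 against shGFP, 1495 and 1052 for shDnmt3L1 and shDnmt3L2 against the other 3 groups, 1355 for genes called in all 3 hairpins and 2939 for the difference among the 3 hairpins. Leaving out 1 array at a time gave 1370 to 2790 for shDnmt3L1 and 969 to 2259 for shDnmt3L2 against the other 3 groups. The replicate block gave 5642 for Dnmt3l knockdown against shGFP, and array weights were equal within each group.

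Of the 25 lists, 0 were called with an estimated correlation and 20 with fry, which does not compare a list with other genes. The lists whose test direction turned follow with their mean. For list: bivalent homeobox genes it was -0.0227 with cyclic loess, -0.129 with probes detected on all 8 arrays, -0.0755 at a detection p under 0.01, -0.0265 without background correction, -0.0114 without a filter, -0.0308 with normexp, and -0.0370 with fry, at an adjusted p of 0.0203 (0.0203 to 0.999 over its alternatives). For list: primed epiblast it was 0.131 with probes detected on all 8 arrays, 0.0883 without background correction and 0.0773 with normexp. For list: pluripotency it was -0.00999 with cyclic loess and -0.00338 with median scaling, for list: housekeeping 0.0483 with median scaling, and with probes detected on all 8 arrays 0.0401 for list: Wnt targets and -0.272 for list: mesoderm. Leaving out 1 array gave -0.0649 to -0.0274 for list: bivalent homeobox genes, -0.0162 to 0.0265 for list: pluripotency and -0.0257 to 0.0225 for list: Polycomb components.

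Ddit3, pooled knockdown, and Dpp4, pooled knockdown, which moved in opposite directions with different hairpins, had values of 0.0782 and 0.0281 with median scaling, 0.0403 and 0.0542 without background correction and 0.0104 and 0.0151 with normexp, and Ddit3 ran from -0.112 to 0.0201 leaving out 1 array. Without the shDnmt3L1 arrays the values were 0.371 for Ddit3, 0.0754 for Mras, pooled knockdown, 0.627 for Socs3, pooled knockdown, 0.0685 for list: LIF STAT3 targets and -0.0727 for list: bivalent homeobox genes. Without the shDnmt3L2 arrays they were 0.271 for Ddit3, -0.0868 for list: bivalent homeobox genes and -0.0883 for list: pluripotency. Without the shDnmt3L3 arrays they were 0.751 for Dpp4, 0.219 for Fgf5, pooled knockdown, 0.0468 for Slc7a3, pooled knockdown, and 0.483 for list: primed epiblast, at an adjusted p of 0.0032 (0.0032 to 0.992 over its alternatives).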

Other observations

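A further 10 gene lists were chosen after the data were seen, and share members such as Serpinh1, Col4a1, Lefty1 and B2m with genes already named, so they are not independent of the results above. Over the 3 hairpins, genes of collagen synthesis and the secretory matrix were higher (10 rose and 1 fell of 14, camera adjusted p = 0.00727, and 0.214 with an estimated correlation), including the prolyl hydroxylases P4ha1 (0.76 ± 0.10, not passing with shDnmt3L2 at 0.35) and P4ha2 (0.67 ± 0.06, log2 ± SE) and the lysyl hydroxylase Plod2 (0.44 ± 0.06). Lysosome and autophagy genes were higher (9 and 1 of 15, 0.0328, and 0.214 with an estimated correlation), including Map1lc3b, a component of autophagosomes (1.06 ± 0.10), Lamp1 (0.88 ± 0.07), Wipi1 (0.67 ± 0.09, not passing with shDnmt3L2 at 0.23) and the protease Ctsb (0.62 ± 0.08). This list was not called with shDnmt3L1 (0.0544) or with shDnmt3L2 (4 rose and 2 fell, 0.313), and was higher with shDnmt3L3 than with the mean of the other hairpins (0.0194, and 0.211 with an estimated correlation). Genes of NODAL signalling were higher (5 and 0 of 10, 0.0389, and 0.251 with an estimated correlation), including Lefty2 (1.00 ± 0.06), the receptor Acvr2b (0.81 ± 0.06) and Smad3 (0.66 ± 0.07). With shDnmt3L3 the NODAL list was not called (4 rose and 3 fell, 0.644), Lefty1 had -0.07 and Nodal fell (-0.59), and the list was lower than with the mean of the other hairpins (0.0194, and 0.231 with an estimated correlation). Genes of the NRF2 and glutathione response were lower (0 rose and 6 fell of 11, 0.0389, and 0.214 with an estimated correlation), including Gsta3 (-1.26 ± 0.07), Hmox1 (-0.86 ± 0.16) and Nqo1 (-0.77 ± 0.08). That list was not called with shDnmt3L1 (0.0842) or shDnmt3L3 (0.140).

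The other added lists were not called over the 3 hairpins. Camera adjusted p was 0.151 for cholesterol synthesis, 0.151 for antigen presentation (Psmb10, an immunoproteasome subunit, -1.40 ± 0.07), 0.177 for the hypoxia response, 0.374 for oxidative phosphorylation, 0.374 for BMP targets (Id3 -1.22 ± 0.14 and Id1 -0.62 ± 0.08) and 0.553 for heat shock (Bag3 1.03 ± 0.07 and Hspb1 -0.43 ± 0.07, with 0.08, not passing, for shDnmt3L3). With shDnmt3L2 against shGFP, cholesterol synthesis genes were lower (0 rose and 10 fell of 18, 0.00084, and 0.131 with an estimated correlation), with Msmo1 at -0.75 there and at 0.49 with shDnmt3L3. With shDnmt3L1, 2 rose and 5 fell (0.470), and shDnmt3L2 was not tested against the other hairpins for this list. With shDnmt3L3 set against the mean of the other hairpins, cholesterol synthesis (10 higher and 2 lower, 0.0194, and 0.211 with an estimated correlation) and oxidative phosphorylation (8 higher and 2 lower of 30, 0.0231, and 0.231 with an estimated correlation) were higher. Vegfa, the endothelial growth factor, rose by 1.51 ± 0.08 with shDnmt3L3.

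Median changes per chromosome lay between -0.12 and 0.11 on the log2 scale over 20 chromosomes and 10911 genes. In a check that uses each array in 1 difference, shDnmt3L3 minus shDnmt3L1 correlated at -0.246 with shDnmt3L2 minus shGFP across genes, and 43.1% of 10930 genes had the same sign. The differences between the 2 arrays of a group correlated at -0.0105 to 0.0373 between groups across genes, so no effect shared by arrays of the same replicate number was seen. Whether the arrays were paired is not given in the labels.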
